A study of Homo sapiens with 6 samples.

How the data were processed

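RNA was measured in 6 libraries labelled as ChIRP, from SK-Hep1 cells, a human liver cancer line. ChIRP pulls down an RNA and what is crosslinked to it with biotinylated antisense DNA probes. In 3 libraries the probes tiled SNHG10, a long noncoding RNA that hosts the small Cajal body RNA SCARNA13, and in 3 control libraries they targeted LacZ, a bacterial gene that human cells lack. Groups and replicate numbers came from the labels. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

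The deposited values are FPKM per transcript, per the file headers. Reads were aligned to hg19 with Bowtie2 2.1.0, per the submitters' processing notes; the program that estimated FPKM was not given in the sources used here. The labels' protocol describes RNA taken with Trizol and libraries made from total RNA, with no pull-down step, while the series design states that retrieved RNA was sequenced. The sources used here do not settle which RNA fraction was sequenced. Each file listed the same 28768 transcripts of 11593 gene symbols, all marked protein coding, and the lowest maximum over the 6 libraries was 0.507 FPKM. SNHG10, SCARNA13 and MYB were not among the rows and were not analysed here, nor were noncoding RNAs. The low values reached 5e-06 FPKM, and 159 lay between 0 and 0.001, lower than a whole read would give in these transcripts, so the depth is unknown. No interval or detection limit was computed for that reason, and FPKM are relative to each library's own total. A value of 0 can be a failed estimate, because RRM1, which dividing cells use, was listed at 0 in 1 library and at 1.4e-05 FPKM in another. Such genes are described by the value of each library.

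FPKM were summed over the transcripts of a gene symbol. Genes with at least 1 FPKM in at least 3 libraries (10304) were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(FPKM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. All log2 differences are on that log2(FPKM + 1) scale, which understates changes of low genes, and are given as SNHG10 probes minus LacZ probes. Transcript rows were tested in the same way (16618 rows). Single values were compared by a two-sided exact permutation test over the 20 assignments of libraries, whose smallest possible p is 0.1. Of 31 gene lists, 20 with at least 5 tested members were tested with camera at a preset correlation of 0.01, and 6 had no listed member. The lists, tests, other settings to be tried and the rule for naming genes were fixed before the data were examined. That rule named the study genes wherever measured, genes past the threshold with fully separated libraries or, failing that, the 5 per direction with the smallest unadjusted p and that separation, the 3 members of each list with the smallest p, and the 5 genes with the highest mean. Some genes that this rule names are not reported here.

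The fit was tested on simulated data, made by shuffling the values of each row over the libraries and multiplying 50 genes per fold size in one probe set. Each simulation thus held 200 changed genes, and recovery with fewer changed genes was not simulated. Of genes raised 2-fold, 4-fold, 8-fold and 16-fold, 9.8%, 49.6%, 76.6% and 85% were recovered among 10304 genes. Among 16618 transcript rows the shares were 2%, 11.6%, 27.2% and 41.8%. Unchanged rows were called too, a median of 8.5 genes (up to 14) or 30.5 transcript rows (up to 39) per simulation. That was a median of 7.4% of the called genes (4% to 12%) and 42% of the called transcript rows (26.8% to 49.4%), above the 5% aimed at. Alternatives were a replicate block, each library left out, other filters, median-ratio and quantile scaling, limma without trend, robust eBayes, pseudocounts of 0.1 and 5, camera with an estimated correlation, and fry. Transcript rows under these settings, and genes with a mean of at least 20 FPKM, were added after seeing the data. pandas 2.3.3 and scipy 1.17.1 were used for shares and exact tests.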

Results

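The series asked which messenger RNAs come down with SNHG10 in SK-Hep1 cells, by comparing 3 libraries made with SNHG10 probes and 3 made with LacZ probes. FPKM totals ran from 268794 to 272909 with SNHG10 probes and from 271354 to 277118 with LacZ probes. Of the 28768 listed transcripts, 30.5% to 33.8% were at 0 in a library, and 11106 were above 0 in all 6. Genes at 0 numbered 850, 897 and 859 in the SNHG10 libraries and 842, 797 and 748 in the LacZ libraries. Genes at 1 FPKM or more numbered 9862 to 9914 and 9963 to 10087. Both counts separated the probe sets fully. The read depth behind the values is unknown. Gene values correlated across genes at a mean Pearson r of 0.893 among SNHG10 libraries, 0.894 among LacZ libraries and 0.891 between the probe sets, on log2(FPKM + 1) values. Genes are not independent replicates, so these are descriptions of library pairs.

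The 5 most abundant messenger RNAs with both probe sets were mitochondrially encoded subunits of the respiratory chain. MT-CO1 averaged 6908 ± 135 FPKM with SNHG10 probes and 6889 ± 237 with LacZ probes (SD, n = 3 each). MT-CO3 averaged 6256 ± 109 and 5994 ± 269, MT-CO2 4716 ± 126 and 4567 ± 230, MT-ND4L 4655 ± 255 and 4212 ± 243, and MT-CYB 3016 ± 68.8 and 2872 ± 18.0. None of these 5 passed the limma test, with adjusted p from 0.885 to 0.993. The 13 mitochondrially encoded transcripts held 14.01%, 14.05% and 13.98% of the FPKM total in the SNHG10 libraries, and 13.43%, 13.35% and 12.81% in the LacZ libraries. The difference of 0.815 percentage points separated the probe sets fully, at the smallest p of the exact test, 0.1. Without the 10 most abundant genes, the 5 remaining members held 2.23% and 2.00%, also separated (exact p = 0.1). Ribosomal protein mRNAs held 10.01% ± 0.238 and 9.92% ± 0.125 (exact p = 0.7), and histone mRNAs 7.05% ± 0.189 and 6.89% ± 0.254 (exact p = 0.5, n = 3 each). The 10 most abundant genes held 13.6% ± 0.0764 and 13.0% ± 0.382 (exact p = 0.1).

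**Figure D1:**
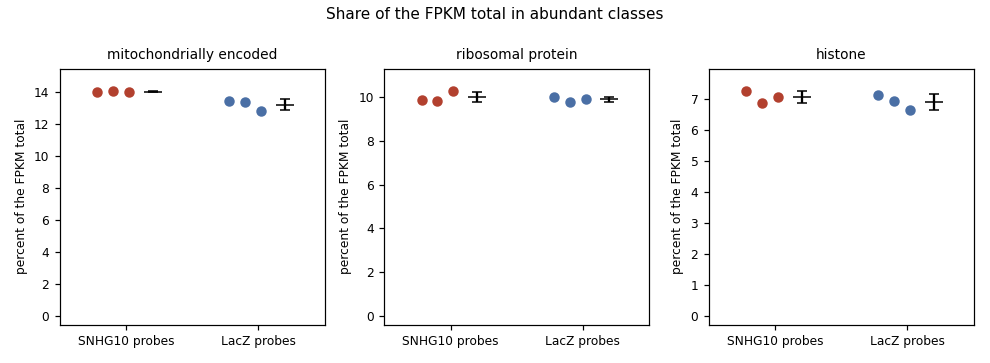
Percent of the FPKM total (vertical axis, from 0) held by mitochondrially encoded, ribosomal protein and histone mRNAs in each library, as points by probe set, with the mean and SD beside them. The 3 SNHG10 libraries lie above the 3 LacZ libraries for mitochondrially encoded transcripts, and the points overlap for the other classes.

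RPL4, a protein of the large ribosomal subunit, and SOX9, a transcription factor of progenitor cells, were the study genes measured. RPL4 (chromosome 15, 66790353 to 66797221, minus strand, hg19) read 61.1, 142 and 156 FPKM with SNHG10 probes and 45.8, 119 and 49.5 with LacZ probes. Its log2 difference was 0.77 ± 0.45 (SE), with overlapping libraries and an adjusted p of 0.928 by limma (exact permutation p = 0.2). Over leave-one-out runs it ranged from 0.52 without SNHG10 replicate 3 to 1.19 without SNHG10 replicate 1 and 1.20 without LacZ replicate 2, and none passed the threshold. SOX9 (chromosome 17, 70117161 to 70122561, plus strand) averaged 44.8 ± 3.29 and 45.9 ± 4.36 FPKM (SD, n = 3 each; exact permutation p = 0.7), with a log2 difference of -0.03 ± 0.15 and an adjusted p of 0.983. Adjusted over the list alone, the limma adjusted p was 0.257 for RPL4 and 0.828 for SOX9. If the study chose these genes on these samples, that is not independent evidence. A shorter listed transcript, RPL4-216 (chromosome 15, 66794123 to 66797183), read 15.2, 11.7 and 9.26 FPKM with SNHG10 probes and was listed at 0 in all 3 LacZ libraries. It missed the threshold among transcript rows (adjusted p = 0.0571 by limma, exact p = 0.1), and passed it only in limma without trend (0.0207), with a range over the alternatives up to 0.659. The longer RPL4-201 read 45.9, 131 and 147 FPKM against 45.8, 119 and 49.5, and held most of the difference in the sum (36.5 FPKM between means, against 12.04 for RPL4-216).

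**Figure D2:**
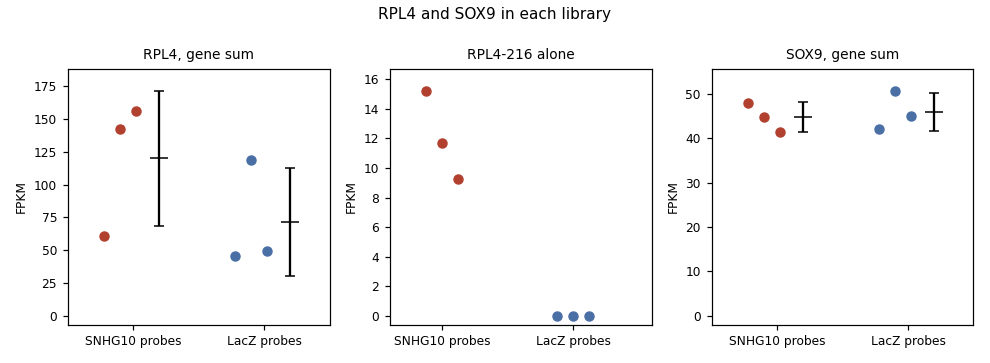
FPKM (vertical axis) of the RPL4 gene sum, of transcript RPL4-216 and of the SOX9 gene sum in each library by probe set, with mean and SD beside the points of the sums. RPL4-216 is listed at 0 in the 3 LacZ libraries and lies between 9.26 and 15.2 in the SNHG10 libraries, while the RPL4 and SOX9 sums overlap.

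No gene was higher or lower with SNHG10 probes at the threshold. Of 10304 genes tested with limma, 0 were higher and 0 lower, with a smallest adjusted p of 0.316, and 558 had an unadjusted p under 0.05 where 515.2 would be the chance number. Of those 558, 216 were higher and 342 lower. The median log2 difference over all genes tested was -0.0537, and -0.00267 with median-ratio scaling, so sign counts within lists hold that small shift. The fit with median-ratio scaling had its own 546 genes under 0.05, 293 higher and 253 lower. The count of 0 was also found with limma without trend (574 genes under 0.05) and with robust eBayes (544). Without SNHG10 replicate 1, 1 gene was lower, RRM1 (adjusted p = 0.0346 by limma). Without LacZ replicate 2, 1 gene was higher, HIST2H4B (0.00181), a histone gene with a near-identical copy, HIST2H4A. Reads could be shared between the copies, but their sum also separated the probe sets (exact p = 0.1). The 3 libraries of one probe set lay all above or all below the other in 1178 genes (11.4%, against 10% by chance). The median SD within a probe set was 0.40 on the log2 scale.

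The genes nearest to the threshold were mostly read at or near 0 in one probe set, and none passed. The chloride transporter SLC12A5 read 9.04, 3.65 and 6.20 FPKM with SNHG10 probes, FSBP 6.16, 7.40 and 2.75, LXN, an inhibitor of carboxypeptidases, 2.55, 3.95 and 5.58, and SVBP, a partner of vasohibins, 6.07, 2.22 and 3.42. All 4 were listed at 0 in the LacZ libraries. DNLZ, a partner of the mitochondrial chaperone HSPA9, read 14.1, 7.65 and 4.86 against 0, 0.815 and 0. Their adjusted p ran from 0.316 to 0.584. With LacZ probes, SDHA, a subunit of succinate dehydrogenase, read 8.69, 11.3 and 20.5 FPKM against 0.774, 0.068 and 0.227 with SNHG10 probes. DDTL read 9.23, 4.06 and 7.71 against 0 in each SNHG10 library, and WDR54 5.34, 7.33 and 8.22 against 0.022, 0 and 0.757. The postsynaptic protein NRGN read 9.71, 6.24 and 9.64 against 1.119, 1.11 and 1.63, a log2 difference of -2.04 ± 0.32, and SEC24C, a coat protein of COPII vesicles, 16.3, 27.1 and 30.3 against 2.44, 0.702 and 5.70. Adjusted p of these 5 ran from 0.316 to 0.560. SDHA has pseudogene copies and DDTL lies beside its close copy DDT, so reads could be split in these genes. The sum of DDT and DDTL was 57.5 ± 2.35 against 55.8 ± 12.4 FPKM (exact p = 0.8, n = 3 each).

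None of the 20 gene lists tested with camera passed the threshold. The smallest adjusted p was 0.641, and 0.810 with an estimated correlation. fry also called 0, with a smallest adjusted p of 0.0887. No member of any list passed over all genes tested. Adjusted over the list alone, with no correction across lists, 1 member passed in each of 4 lists, 1 of them too small for camera. MT-ND3, a subunit of complex I, was higher with SNHG10 probes (1421, 1519 and 1472 against 1146, 1196 and 1153 FPKM, limma adjusted p = 0.00958, log2 difference 0.34 ± 0.06). It was not called without LacZ replicate 1 (0.0519) or in limma without trend (0.982). SDHA among nuclear-encoded respiratory chain genes (0.00295) and EGFL7, a secreted endothelial protein (8.30, 7.45 and 8.18 against 26.0, 18.8 and 14.0 FPKM, 0.00793), were lower, and stayed past the threshold over the list in the 15 alternatives that tested them. The endothelial list held only 3 tested members, and ROBO4 (0.23) and ENG (0.04) had positive log2 differences. Over all genes, the limma adjusted p of EGFL7 was 0.778. FAU, which encodes ribosomal protein S30, was lower (118, 104 and 110 against 174, 161 and 168 FPKM, log2 difference -0.60 ± 0.11, limma adjusted p = 0.0179), with a range of 0.0177 to 0.559 over the alternatives. It was called in 11 of 16 alternatives, and lost among others without SNHG10 replicate 2, SNHG10 replicate 3 or LacZ replicate 3, where p reached 0.0838, or in limma without trend.

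Ribosomal protein mRNAs were abundant and did not pass as groups. Of 50 large-subunit members, 22 had a positive and 28 a negative log2 difference, which turned to 30 and 20 with median-ratio scaling, and none passed over the list alone. RPL27 read 587, 603 and 574 FPKM against 531, 507 and 454, RPL30 454, 411 and 462 against 511, 576 and 488, and RPLP2 293, 338 and 331 against 294, 257 and 246. Of 33 small-subunit members, 15 were positive and 18 negative (17 and 16 with median-ratio scaling). RPS3 read 157, 167 and 142 against 77.7, 135 and 91.1, and the laminin receptor RPSA 544, 746 and 697 against 462, 489 and 564. Among 46 tested histone mRNAs, 22 were positive and 24 negative (27 and 19 with median-ratio scaling). HIST2H4A read 553, 514 and 549 against 483, 438 and 416, HIST2H2BF 160, 149 and 145 against 187, 198 and 185, and HIST1H1A 2.05, 6.47 and 8.31 against 10.7, 26.7 and 17.8.

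Processing and RNA-handling genes did not pass either. NOP56, a core protein of box C/D snoRNPs, read 26.6, 26.3 and 24.5 FPKM against 21.9, 16 and 16.1, TCOF1 23.1, 34.5 and 26.3 against 21.0, 21.9 and 18.7, and NAF1 3.06, 3.42 and 1.42 against 9.84, 2.88 and 6.06. Of 73 spliceosome and hnRNP genes, 27 were positive and 46 negative (30 and 43 with median-ratio scaling). Those with the smallest p by limma were HNRNPD (34.4, 35.0 and 49.6 against 54.5, 61.7 and 66.4), HNRNPH3 and HNRNPLL. The snoRNA hosts CWF19L1 and TAF1D read 1.07 to 4.20 and 0 to 4.89 FPKM with SNHG10 probes, against 1.15 to 12.3 and 2.26 to 4.09. Of 34 translation factors, 13 were positive and 21 negative (19 and 15 with median-ratio scaling). EIF3G read 52.8, 40.0 and 53.0 against 56.5, 62.4 and 68.9.

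Pathways named for the study gave no call. Of 9 MYB-linked genes, CCNB1, which drives entry into mitosis, read 75.6, 84.3 and 87.3 FPKM against 55.0, 62.3 and 77.9, GATA3 13.8, 15.4 and 21.9 against 23.5, 19.8 and 22, and CCNE1 4.11, 0 and 2.76 against 4.74, 6.38 and 5.65. Of 10 reported miR-150-5p targets, PIM1 read 30.2, 37.6 and 29.4 against 25.8, 22.4 and 33.5, and ELK1 20.3, 29.3 and 18.6 against 30.2, 24.3 and 22.3. Of 19 Wnt and SOX9 pathway genes, 11 were positive and 8 negative (13 and 6 with median-ratio scaling). DVL1 read 19.7, 26.4 and 26.1 against 28.9, 35.9 and 37.2, and DVL2 35.4, 29.7 and 40.1 against 28.9, 26.7 and 25.4. Of 31 cell-cycle genes, 9 were positive and 22 negative (17 and 14 with median-ratio scaling). RRM1, a subunit of ribonucleotide reductase, read 15.3, 0 and 1.4e-05 against 20.6, 18.0 and 23.5. E2F1 read 4.33, 3.70 and 6.17 against 12, 10.2 and 5.67. Of 15 glycolysis genes, 4 were positive and 11 negative (5 and 10 with median-ratio scaling). PFKP read 149, 149 and 141 against 179, 183 and 178. Of 19 very long mRNAs, 5 were positive and 14 negative (7 and 12 with median-ratio scaling). MACF1 read 88.1, 97.0 and 93.2 against 147, 126 and 106.

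Epithelial and mesenchymal markers ranged from abundant to low and gave no call. KRT8, a keratin of simple epithelia, read 549, 544 and 465 FPKM against 601, 589 and 633, and VIM, the mesenchymal intermediate filament, 1202, 846 and 833 against 1443, 1522 and 953. Of 18 epithelial-mesenchymal genes, 10 were positive and 8 negative. TAGLN read 9.55, 1.93 and 21.0 against 1.72, 1.38 and 1.99, and ZEB2 3.91, 5.24 and 5.43 against 5.27, 13.2 and 19.8. KRT7, of biliary cells, read 13.9, 18.1 and 21.6 against 20.8, 21.1 and 17.5. Of leukocyte markers, CD68 read 54.4, 53.0 and 35.3 against 43.8, 54.2 and 42.3, and CD14 was between 0.763 and 2.69 FPKM in all 6 libraries. The endothelial marker ENG read 41.8, 33.6 and 32.4 against 32.7, 41.8 and 30.7. ACTA2 read 22.1, 7.70 and 23.0 against 40.8, 27.4 and 22, and COL3A1 27.6, 24.1 and 27.5 against 17.5, 18.3 and 24.8. Of the hepatocyte markers, CPS1 and SERPINA1 were listed, at 0.505 to 1.53 and 0 to 1.24 FPKM.

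Among 16618 transcript rows, 8 were higher and 7 lower with SNHG10 probes past the threshold of limma, while 0 of their 15 genes passed. In simulated data a median of 42% of the transcript rows called were false, so the threshold of 0.05 was not held there. Those simulations held 200 changed rows each, so that share does not carry over to these 15 calls. In 100 shuffles of each row's values, with no row changed, a median of 7 rows was called (0 to 28). The 8 higher rows were each listed at 0 in all 3 LacZ libraries, and included transcripts of GRN, CNN2, TCAF1, ATXN2L, OXA1L, POLDIP2 and CAP1. The 7 were transcripts of MYOF, RPL9, FAM83D, KHDRBS1 and MSANTD3, listed at 0 in all 3 SNHG10 libraries, and of S100A16 and KPNB1, at most 0.435 FPKM there. MYOF-201, of the membrane repair protein myoferlin, was listed at 0 in each SNHG10 library and read 29.1, 55.0 and 49.5 with LacZ probes, while MYOF-202, with the same start and end (chromosome 10, 95066187 to 95241951), read 151, 154 and 162 against 129, 101 and 114. In 14 of the 15 genes, the other listed transcripts together moved the opposite way. Gene sums moved with the called transcript by -0.327 to 1.11 (log2), and by at most 0.5 either way in 10 of the 15. The log2 difference of the sums was 0.13 for GRN and -0.07 for MYOF, but -1.11 for MSANTD3, 0.875 for TCAF1, -0.666 for FAM83D, 0.510 for OXA1L and -0.505 for KPNB1. All 15 calls were lost, with 0 rows past the threshold, when any 1 of the 6 libraries was left out (915 to 992 rows at an unadjusted p under 0.05). With the replicate number as a block, 0 of the 15 remained. The smallest limma adjusted p was 0.0625 to 0.161 over the leave-one-out runs and 0.545 with the block. These fits have fewer libraries or more terms, so the losses cannot tell dependence on single libraries from lower power. limma without trend called 53 rows, and a pseudocount of 0.1 or of 5 left 5. Median-ratio and quantile scaling each kept all 15, and robust eBayes kept 13.

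**Figure D3:**
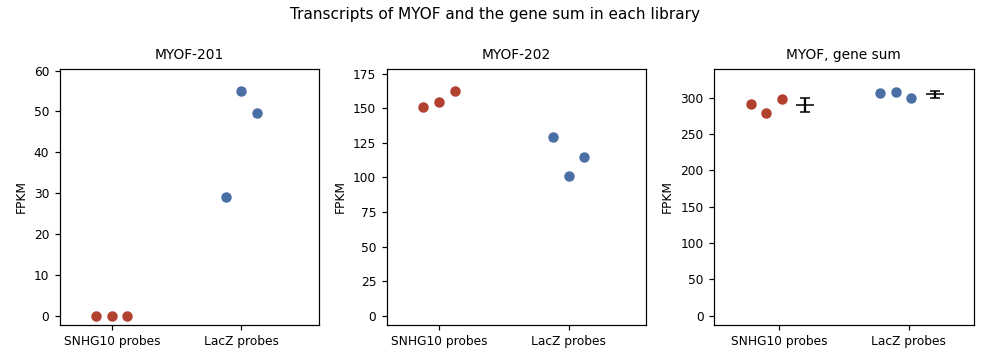
FPKM (vertical axis) of MYOF-201, MYOF-202 and the sum of all listed MYOF transcripts in each library by probe set, with mean and SD beside the points of the sum. MYOF-201 is listed at 0 with SNHG10 probes and lies between 29.1 and 55.0 with LacZ probes, while MYOF-202 is higher with SNHG10 probes.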

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

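The transcript-row settings and the genes with a mean of at least 20 FPKM were added after seeing the data. No value for SNHG10 itself could be computed. Genes tested one by one gave 0 higher and 0 lower in every setting but leave-one-out: the range was 0 to 1 higher, 0 to 1 at least 2-fold higher and 0 to 1 lower, with RRM1 lower without SNHG10 replicate 1 (-4.43, adjusted p = 0.0346) and HIST2H4B higher without LacZ replicate 2. The numbers of called lists stayed at 0. Unsummed transcript rows gave 8 higher, 8 of them at least 2-fold, and 7 lower. Those rows gave the same 8 and 7 with median-ratio and with quantile scaling, and 7 and 6 with robust eBayes. They gave 3 and 3 with no filter and with at least 5 FPKM, and 26 and 27 without trend. A pseudocount of 0.1 and of 5 gave 3 and 2, and every leave-one-out run 0 and 0. The cause was not tested. All 15 calls were among the 53 without trend. With the replicate number as a block, 0 and 0 transcript rows and 0 genes were called, and FAU no longer passed over its list (limma adjusted p = 0.0675). Deviations of same-numbered libraries correlated at 0.015, 0.012 and 0.016, under 0.1, so the numbers were not read as pairs, although every sample correlated best with its own number at the gene level, a hint from the data only.

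Signs of values near 0 turned. SOX9 was 0.0256 with median-ratio scaling and 0.01 with quantile normalization, and -0.0932 to 0.038 over leave-one-out runs (0.0201 without SNHG10 replicate 3). MT-CO2 was -0.0652 with quantile normalization, and over leave-one-out runs MT-CO1 ranged from -0.0223 to 0.027, CD68 from -0.1014 to 0.2027, ENG from -0.072 to 0.1684 and KRT7 from -0.298 to 0.0056. The mitochondrial share difference was 0.228 points without the 10 most abundant genes, 8 of which are mitochondrial. The cause of other changes was not tested. Of 1421 alternative values, 1373 were labelled the same as in the main fit. For genes that meant the same direction and side of the threshold. For counts it meant an equal or similar number, and for shares a difference moved by less than the SD. Several settings leave a gene's log2 difference unchanged by construction, and most genes lay far from the threshold, so much of that sameness was fixed beforehand. Unknown depth limits what low values can show.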

Other observations

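The shuffles of transcript values were chosen only after the result was seen. Several groups not yet described held values that did not pass the test. CHOP, the stress factor encoded by DDIT3, read 13.2, 18.0 and 13.9 FPKM with SNHG10 probes and 19.9, 28.5 and 21.0 with LacZ probes, and FOSB 4.77, 3.22 and 6.63 against 8.75, 9.27 and 7.39. The proteasome subunit PSMD9 read 28.3, 35.8 and 35.9 against 18.0, 25.0 and 21.7, while PSMB10 read 0.590, 0.605 and 0 against 1.82, 1.56 and 2.33. Of 37 proteasome genes, 18 were positive and 19 negative (21 and 16 with median-ratio scaling). MRPL40, of the mitochondrial ribosome, read 12.2, 13.1 and 13.8 against 6.80, 7.89 and 5.89, and MRPL3 18.2, 19.6 and 26.5 against 42.0, 52.2 and 27.0. Of 77 such genes, 38 were positive and 39 negative (41 and 36 with that scaling). Of 68 nuclear-encoded respiratory chain genes, 38 were positive and 30 negative. ATP5D, of ATP synthase, read 58.3, 58.3 and 63.2 against 46.8, 43.3 and 43.8.

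GAPDH, a glycolytic enzyme, read 1647 and 2031 FPKM in SNHG10 replicate 2 and LacZ replicate 2, and 836 to 984 in the other 4 libraries. MYC, a growth regulator, read 67.6 and 58.5 in the same libraries and 22.5 to 42.5 elsewhere. Of 364 genes with a mean of at least 100 FPKM, 28 (7.69%) had a 2-fold range within a probe set, among them ACTB, AHNAK, PTMA and RPL7A. AHNAK, a very large scaffold protein, read 298, 57.9 and 270 FPKM with SNHG10 probes and 272, 263 and 96.8 with LacZ probes. These genes were chosen after their values were seen.

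HIST2H4B, a histone H4 gene with a near-identical copy, HIST2H4A, read 337, 324 and 318 FPKM with SNHG10 probes and 3.72, 260 and 7.74 with LacZ probes. Summed, the copies read 890, 838 and 868 against 487, 698 and 423 (exact p = 0.1, the smallest possible). HIST2H4A itself read 483, 438 and 416 in LacZ replicates 1, 2 and 3. It held no gain of the size that HIST2H4B lost in replicates 1 and 3. These values argue against exchange of reads between the copies as the whole account.

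The 15 called transcripts would be the pull-down's result at isoform level. Transcripts at 1 FPKM or more in the 3 SNHG10 libraries and listed at 0 in the others numbered 70. The 19 other choices of 3 libraries gave 55 to 94, so no excess was seen with SNHG10 probes. That number cannot decide on recovery of single isoforms, because a few, such as the 8 called higher, need not raise it past 94. Gene sums moved with the called transcript by a median of 0.225 (log2), under the bound of 0.5 set for movement of FPKM between transcripts. That cannot decide it where the called transcript was a small part of its gene. MYOF-201 read 29.1 to 55.0 FPKM with LacZ probes, beside 129 to 142 for MYOF-204, so its loss could not move the sum past the bound. The other transcripts together moved the opposite way in 14 of the 15 genes, so such movement may account for part of the calls. In 5 of the 15 genes the sum moved by more than that bound. The bound was set for the median and no sum of the 15 genes passed the threshold, so those 5 genes cannot decide it either. Zeros were scattered alike within and between probe sets (a difference of -0.004 percentage points in the share of transcripts at 5 FPKM or more listed at 0 elsewhere). That share ran from 12.47% to 15.15% over pairs within a probe set. The 15 called rows are too few to move it past that range, so it cannot decide on them. Of 100 shuffles of each transcript's values, 17 gave as many calls. Of the 10 splits of the libraries, 3 gave as many calls (15 for the real one, up to 20 for others). The real split had the most transcript rows at an unadjusted p under 0.05, 940 against 841 to 935, and 10 splits are too few for a share under 0.05.

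The absence of called genes may reflect a pull-down whose enrichment of messenger RNA was below what 3 libraries can show. The fit recovered 76.6% of genes changed 8-fold, between the bounds of 50% and 80% set for deciding. Low power at that size thus stays open over genes of all levels together. Recovery by level was not simulated. The median SD within a probe set (log2) was 0.53 for genes under 5 FPKM and 0.15 for those over 100. The 76.6% came from simulations with 200 changed genes each, and the adjustment is harder to pass when fewer genes change. SDHA averaged 0.356 FPKM with SNHG10 probes and 13.5 with LacZ probes, with a limma adjusted p of 0.316. Total RNA in all 6 libraries, as the labels' protocol describes, would also leave no gene to call, and was not tested. With 0 called genes for the real split, all 10 splits give as many whatever the data (up to 2 for others), so that count decides nothing. The real split had the most genes at an unadjusted p under 0.05, 558 against 462 to 527, which is 1 of 10 and leaves a weak difference between the probe sets open. No measured row could serve as a check of the bait.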
